A study of Mus musculus with 13 samples.

How the data were processed

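RNA from mouse retina was measured on 13 Agilent gene expression arrays. The labels divide the samples into 6 tip samples, 4 stalk samples and 3 control samples of nonvascular retina. Each array carried the sample in Cy5 (red) and a common reference, Universal Mouse Reference RNA, in Cy3 (green), with no dye swap, per the labels. RNA was extracted with the Arcturus PicoPure kit, checked on a Bioanalyzer and labelled with a low input linear amplification kit, per the labels' protocols. The labels do not state how the cells were collected. They also do not tie samples to animals, so every p-value measures only the spread between these samples, and part of that spread may be technical.

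Per the file headers, the arrays were read with Agilent Feature Extraction 8.5.1.1, which gives for each spot and channel the mean pixel intensity and the median intensity of the local background, neither of them normalized. Per the file headers, the processed intensity of a spot has a spatial background surface subtracted, is normalized between the dyes with linear and LOWESS factors, and is replaced by a surrogate where it is not above background. The log10 ratio in the same files is that of the processed red over the processed green signal, per the file headers. The deposited value table holds linear red over green ratios. On each array at least 99.94% of its probes equalled the antilog of the log10 ratio within 0.001 on the log10 scale, and 631 to 1555 probes were missing.

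Each array has 43790 spots, of which 41534 are not controls, and these hold 41174 different probes. Gene names came from a RefSeq gene table (assembly GRCm38.p6), which was used for names only: 22072 probes were matched through their own accession, 135 through another RefSeq accession and 1094 through the symbol in their description. The other 17873 probes kept the name in the files. No coordinates are given, because the files do not name a genome build.

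Log2 ratios of sample over reference were computed from the mean intensities and local backgrounds, not from the processed signals. Background was corrected with the normexp method (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3 with data.table (1.17.8). Control spots had weight 0 in loess and were left out, and spots marked as outliers in the files were set to missing. Repeated spots of a probe were averaged. The probe with the highest mean intensity stood for its gene, and genes had to be well above background in the red channel on at least 3 of the 13 arrays. This left 32050 genes, 16550 of them with a symbol. The median red signal over background per array was 98.1 to 292, and 85.0% to 95.4% of spots were well above background in red. The number of arrays limits the precision.

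A linear model with 3 group means was fitted to all 13 arrays with limma's moderated test, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. The 3 groups share one estimate of a gene's spread, so nonvascular arrays that differ among themselves also raise the error of tip minus stalk. Genes with an adjusted p under 0.05 were called. The differences are tip minus stalk, tip minus nonvascular retina and stalk minus nonvascular retina, all on the log2 scale, and errors on them are standard errors from limma. Group values are means with the SD over arrays.

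The design, the 27 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those described here or later as added. The lists cover vessel cells (tip cell markers, stalk and Notch pathway, pan-endothelial, arterial, venous, pericyte and smooth muscle, blood-retina barrier), other retinal cells (astrocyte, Mueller glia, microglia and macrophage, ganglion cell, photoreceptor, amacrine with horizontal and bipolar cells, erythroid, lens crystallin) and processes (cell cycle, matrix, proteases, VEGF family, axon guidance, hypoxia response, chemokines, TGF-beta and BMP, Norrin and Wnt, filopodia and actin, immediate early and heat shock, ribosomal proteins). Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists of a comparison. Camera with a correlation estimated per list and fry served as alternatives. Members were counted as higher or lower both over all genes and adjusted over the list alone. The named genes are 14 fixed ones, the 8 largest called differences per direction that had a symbol and were well above background on every array of the higher group, and up to 3 members with the smallest p of each list that was called or had 3 or more called members. Other names are marked as chosen after their values were seen. The text names only part of the genes this rule gives, and 1 of them was left out of the search for single arrays far from the rest of their group. Another 6 gene families were taken by symbol pattern after the data were seen.

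The steps were tested on simulated data with the real arrays' levels and spread, with 200 genes changed in the tip group. For tip minus stalk, 32 of 50 genes changed by 0.5 on the log2 scale were called in the right direction, as were 48 of 50 changed by 1 and 50 of 50 changed by 2 or by 3, with 16 false calls among 32050 genes. For tip minus nonvascular retina these counts were 34, 47, 50 and 50 of 50, with 10 false calls. A list shifted by 0.5 was called, with a median of 0.53, and 0 other lists were. The simulated genes were drawn independently of each other, so this does not test list calls where genes are correlated.

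The alternatives were the Feature Extraction log ratios, no background subtraction, a normexp offset of 10, median centring in place of loess, Aquantile normalization between arrays, the deposited ratio table, the red channel alone, other filters on dim probes, outlier spots kept, the mean of a gene's probes, other estimates of the spread, only the groups compared, the replicate number as a block, the scan date as a block, and leaving out each array in turn. An array's red brightness as a covariate was added after the data were seen. Every slide held 1 array, so slide and sample cannot be told apart. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.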

Results

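Expression was measured in tip samples (n = 6), stalk samples (n = 4) and nonvascular retina (n = 3) of the mouse, each against a common reference RNA on the same array. Tip cells lead a growing vessel sprout and stalk cells follow behind them. The study looked for genes that set retinal tip cells apart, and the nonvascular samples are labelled as its control. Whether they resemble the retina beside the tips was not tested. The first principal component held 67.2% of the variance and set nonvascular retina (−90.2 to −66.2) apart from stalk (26.8 to 40.0) and tip (15.1 to 25.6). The next component, with 8.86%, placed stalk arrays at −26.7 to −10.9 and tip arrays at −0.475 to 24.6. Across genes, which are not independent replicates, log2 ratios correlated at 0.943 to 0.971 among tip arrays, at 0.945 to 0.958 among stalk arrays and at 0.909 to 0.952 between them. Correlations of nonvascular arrays were 0.952 to 0.976 with each other, 0.657 to 0.806 with stalk and 0.715 to 0.841 with tip. The median red signal over background was 98.1 to 141 in stalk, 105 to 292 in tip and 166 to 282 in nonvascular arrays. Stalk arrays were scanned first, then tip and then nonvascular arrays, with tip replicate 5 last and on another day, so scan order and group cannot be told apart.

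The comparison of tip with stalk addresses which genes distinguish samples labelled tip from those labelled stalk, and both may hold several cell types. Against nonvascular retina, 13 of 19 pericyte genes and 6 of 14 astrocyte genes were higher in tip, with 1 lower in each list. Several genes known from sprouting vessels were among those higher in tip. Esm1, which encodes a proteoglycan secreted by endothelium, stood at a log2 ratio of 4.64 ± 0.27 in tip (SD, n = 6) and 1.77 ± 0.32 in stalk (SD, n = 4), a 7.30-fold difference. Transcripts of the Tie2 ligand Angpt2, the vasoactive peptide Adm and the chemokine receptor Cxcr4 were 3.53-fold, 3.43-fold and 2.76-fold higher. Genes of the barrier that seals retinal vessels went the other way: Mfsd2a, a lipid transporter of barrier endothelium, stood at 0.62 ± 0.22 in tip and 3.59 ± 0.28 in stalk, and the tricellular junction gene Lsr was 8.14-fold lower in tip.

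Of 32050 genes, 469 were higher and 422 lower in tip than in stalk (limma, adjusted p under 0.05), 27 and 89 of them by at least 2-fold, and 5776 had an unadjusted p under 0.05. The naming rule gave 60 genes, of which 53 were called, each with 6 of 6 tip arrays on the same side of the stalk mean. Esm1 had a log2 difference of 2.87 ± 0.16 (SE, adjusted p = 2.76e-06), with stalk replicate 4 at 2.25 above the other stalk arrays (1.59 to 1.65). Cxcr4 differed by 1.47 ± 0.21 (adjusted p = 0.00301), and its other probe by 0.14. The ion channel subunit gene Kcne3 (1.37 ± 0.12, adjusted p = 9.37e-05) and the keratan sulfate sulfotransferase gene Chst1 (1.70 ± 0.10, adjusted p = 2.76e-06) were higher as well. So was Trp53i11, a gene induced by p53, with 1.55 ± 0.19 (adjusted p = 0.00119). Smaller differences were seen for Apln, the ligand of the apelin receptor (0.89 ± 0.12, adjusted p = 0.00201, another probe at −0.07), and for the Notch ligand Dll4 (0.41 ± 0.07, adjusted p = 0.00716). With array brightness in the model, Dll4 had an adjusted p of 0.0903 (range over all alternatives 0.0026 to 0.0903) and Adm one of 0.0675 (0.000285 to 0.0675). Over the alternatives the difference of Dll4 was 0.34 to 0.63 and that of Kcne3 was 0.81 to 2.06, and with the mean of a gene's probes Cxcr4 differed by 0.80 and Apln by 0.575. The VEGF receptor genes Kdr (−0.66 ± 0.21, adjusted p = 0.12) and Flt4 (−0.14 ± 0.04, adjusted p = 0.119) were not called. Kdr was lower in 6 of 6 tip arrays and was called with only the 2 groups compared (adjusted p = 0.0086) and without nonvascular replicate 3 (0.00421, range 0.00421 to 0.584). Neither were Pdgfb, Unc5b, Cdh5, Pecam1 and Cxcl12 called (adjusted p = 0.197, 0.236, 0.709, 0.282 and 0.693), although Pdgfb was called higher with the red channel alone (0.74, adjusted p = 0.0162) and with brightness in the model (0.47, adjusted p = 0.02).

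Among the genes lower in tip, Lsr had a log2 difference of −3.02 ± 0.17 and Mfsd2a one of −2.97 ± 0.15 (both adjusted p = 2.76e-06). The retinoid-binding protein gene Rbp7 (−2.43 ± 0.17, adjusted p = 1.16e-05) and the transporter gene Flvcr2 (−2.27 ± 0.15, adjusted p = 7.67e-06) were lower too. The flow-responsive transcription factor gene Klf4 differed by −2.20 ± 0.17 (adjusted p = 3.33e-05), with tip replicate 1 at −3.44, below the other tip arrays. Gja4, a gap junction gene of arterial endothelium, was lower by 3.77-fold (adjusted p = 0.000157). The Notch ligand gene Jag1 fell by 1.07 ± 0.11 (adjusted p = 0.000285), the Notch target gene Heyl fell by 1.21 ± 0.14 (adjusted p = 0.000593, another probe at 0.01) and the apelin receptor gene Aplnr fell by 0.83 ± 0.07 (adjusted p = 6.07e-05). Flt1, a decoy receptor for VEGF, fell by 0.94 ± 0.11 (adjusted p = 0.000825), with tip replicate 6 at 1.91 below the other tip arrays (2.19 to 2.34). The red channel alone gave Aplnr an adjusted p of 0.136 (range over alternatives 4.57e-05 to 0.136), and median centring gave Apln one of 0.0548 (6.87e-05 to 0.0548). With the mean of a gene's probes Rbp7 differed by −1.27, Heyl by −0.60, Jag1 by −0.58 and Aplnr by −0.49.

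**Figure D1:**
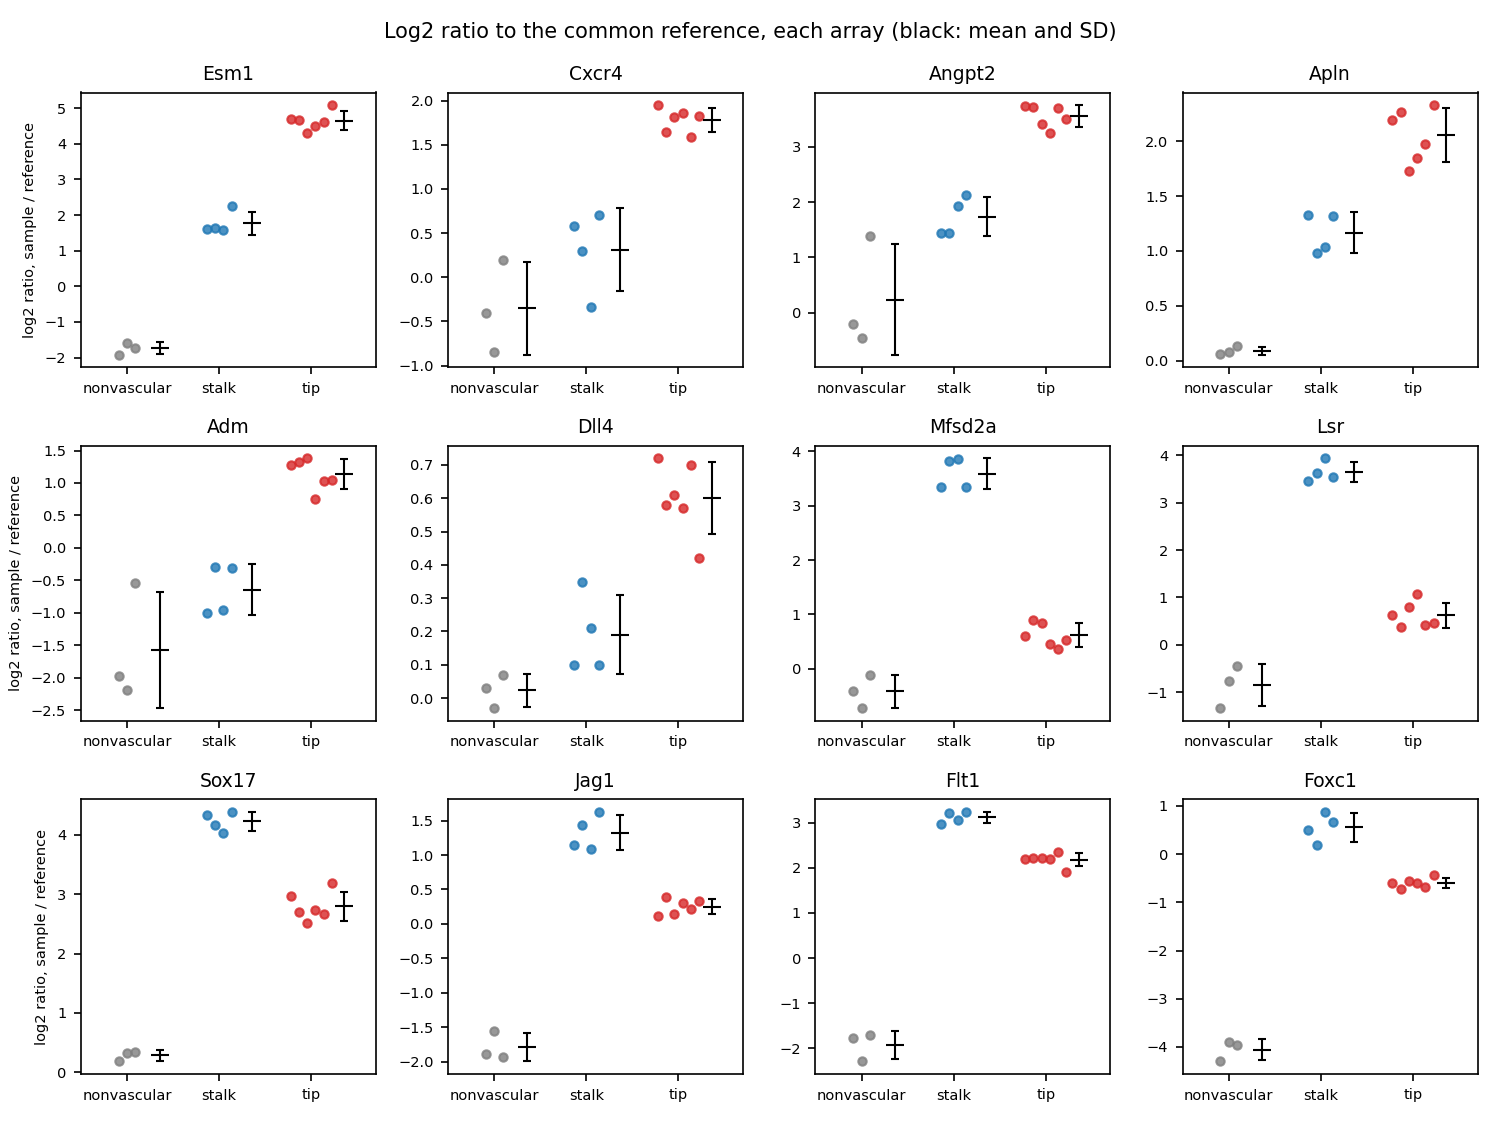
Log2 ratio of sample over reference (vertical axis) of 12 genes in nonvascular retina (3 arrays), stalk (4) and tip (6), 1 point per array, with the mean and SD in black. Esm1 averages 4.64 in tip and 1.77 in stalk, and Mfsd2a 0.62 in tip and 3.59 in stalk.

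Groups of vessel genes moved apart between tip and stalk. Of 22 blood-retina barrier genes, 9 were lower and 0 higher (11 and 2 when adjusted over the list alone, median −0.40, camera adjusted p = 1.36e-10), among them Lsr, Mfsd2a and Itm2a. Of 36 pan-endothelial genes, 8 were lower and 1 higher (15 and 1 over the list alone), among them Sox17 (−1.44 ± 0.12), Calcrl (−1.33 ± 0.12) and Ptprb (−1.52 ± 0.16). Their median was −0.30 (camera adjusted p = 2.44e-11, and 0.033 with an estimated correlation between genes), and 11 of the 36 are in another list. With the mean of a gene's probes Sox17 differed by −0.58 and Calcrl by −0.77. Markers of pericytes, the mural cells that cover retinal vessels, were lower: 9 of 19 fell and 0 rose (12 lower over the list alone, median −0.59, camera adjusted p = 1.95e-11), with Foxc1 at −1.15 ± 0.12, Higd1b at −1.10 ± 0.16 and Vtn at −1.17 ± 0.17. From the Feature Extraction log ratios Higd1b had an adjusted p of 0.124 (range over alternatives 0.000268 to 0.124), and from the red channel alone it differed by −1.79. None of these 19 is in another list. Of 11 arterial genes 3 were lower and 1 higher (6 and 1 over the list alone, median −0.40, adjusted p = 0.0014), among them Gja4 and Fbln5. This call was lost with an estimated correlation between genes (adjusted p = 0.0573), and Fbln5 lost its own with brightness in the model (0.057). Of 11 venous genes 3 were lower and 1 higher (4 and 1 over the list alone, median −0.32, adjusted p = 1.88e-04), among them Aplnr and Nr2f2. This call was lost with the red channel alone (median −0.05, adjusted p = 0.0611). Norrin and Wnt signalling, which maintains the retinal barrier, had 4 of 21 genes lower and 0 higher (8 and 1 over the list alone, median −0.17, adjusted p = 5.14e-05). Its members Lef1 (−1.01 ± 0.19, adjusted p = 0.0157) and Dkk2 (−0.95 ± 0.16, adjusted p = 0.00794) were lower, although Dkk2 was well above background on 2 of 6 tip arrays. Dkk2 ranged from −3.48 to −0.78 over the alternatives. With brightness in the model neither Dkk2 (adjusted p = 0.0533) nor Lef1 (0.123) was called, and Lef1 had an adjusted p of 0.0571 without stalk replicate 1 and of 0.0534 without stalk replicate 3 (range over alternatives 0.00317 to 0.123). Over the alternatives the list medians were −0.72 to −0.33 for barrier, −0.465 to −0.14 for pan-endothelial, −0.77 to −0.30 for pericyte, −0.54 to −0.21 for arterial, −0.44 to −0.05 for venous and −0.38 to −0.08 for Norrin and Wnt genes.

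The tip cell marker list rests partly on earlier studies of tip cells, including this one, and Cxcr4 is in the series title, so its count is not independent evidence. Of its 26 genes, 8 were higher and 1 lower (10 and 4 over the list alone, median 0.27, camera adjusted p = 1.88e-04, and adjusted p = 0.0573 with an estimated correlation), and 18 are in another list. Hypoxia response genes were higher in tip: 6 of 24 rose and 0 fell (11 and 1 over the list alone, median 0.26, adjusted p = 3.55e-06, and adjusted p = 0.0573 with an estimated correlation). Adm, the collagen hydroxylase gene P4ha1 (0.93 ± 0.12, adjusted p = 0.00154) and the glycolytic genes Tpi1 (0.89 ± 0.10, adjusted p = 0.000683) and Pgk1 (0.72 ± 0.11, adjusted p = 0.00578) were among them. With median centring Tpi1 (adjusted p = 0.0911, range 0.000333 to 0.0911) and Pgk1 (0.341, range 0.00373 to 0.341) were no longer called, nor was Pgk1 with brightness in the model (0.0721). Pgk1 differed by 0.48 in the red channel alone, and P4ha1 by 0.60 with the mean of its probes. The stalk and Notch pathway list had 5 of 23 genes lower and 1 higher (6 and 3 over the list alone, median −0.20, adjusted p = 4.2e-04), a call lost with an estimated correlation (adjusted p = 0.196). Matrix genes had 4 of 32 higher and 0 lower (5 over the list alone, median 0.07, adjusted p = 0.0462, and 0.457 with an estimated correlation), among them P4ha1 and the basement membrane gene Nid2 (0.65 ± 0.12, adjusted p = 0.0146). The matrix list lost its call without nonvascular replicate 1 or 3, stalk replicate 1, 2 or 3, or tip replicate 2, 3, 4 or 5 (adjusted p = 0.0505 to 0.099). It was also lost from the Feature Extraction log ratios (0.0532), the deposited ratios (0.0517) or the red channel alone (0.766), without background subtraction (0.0648), with median centring (0.0913), with only the 2 groups compared (0.0561) and with fry, another list test (0.184). Nid2 had an adjusted p of 0.0517 without stalk replicate 1, 0.18 with median centring, 0.0608 with the red channel alone and 0.119 with brightness in the model (range over alternatives 0.00905 to 0.18). The medians over the alternatives were 0.14 to 0.39 for tip cell markers, −0.34 to −0.11 for stalk and Notch genes and 0.01 to 0.16 for matrix genes.

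Lists that were not called in this comparison also had members that passed. Filopodia and actin genes had 3 of 33 higher and 2 lower (7 and 2 over the list alone, median 0.07, adjusted p = 0.0594), with Marcksl1 at 0.47 ± 0.06 and Cdc42ep3 at 0.72 ± 0.12. Marcksl1 was not called with median centring (adjusted p = 0.274) and differed by 0.72 in the red channel alone. This list was called without stalk replicate 4 (adjusted p = 0.0305), without tip replicate 6 (0.0322), from the Feature Extraction log ratios (0.0465) or the deposited ratios (0.0453) and with fry (0.0237). Immediate early and heat shock genes had 3 of 26 higher and 1 lower (5 and 1 over the list alone, median 0.08, adjusted p = 0.0728), among them Ier3 and Klf6, and were called without nonvascular replicate 2 (0.0486), stalk replicate 2 (0.026) or tip replicate 1 (0.018) and from the Feature Extraction log ratios (0.0436) or the deposited ratios (0.0427). With median centring neither Ier3 (adjusted p = 0.0585) nor Klf6 (0.152) was called, nor was Ier3 with brightness in the model (0.134) or Klf6 with the red channel alone (0.16, adjusted p = 0.516). Proteases and inhibitors had 2 of 24 higher and 3 lower (5 and 5 over the list alone, median 0.06, adjusted p = 0.899), the lower ones including Adam15 and Ctsh. Adam15 and Ctsh were not called with median centring (adjusted p = 0.241 and 0.111) or with brightness in the model (0.0617 and 0.1). Axon guidance had 2 of 37 higher and 1 lower (5 and 2, median 0.06, adjusted p = 0.134), with the semaphorin gene Sema3f at 0.49 ± 0.06, and was called with fry (0.0203). The VEGF family had 0 of 10 higher and 1 lower, Flt1 (2 and 3 over the list alone, median −0.09, adjusted p = 0.257, and 0.0206 with fry). Its member Vegfa, chosen here after its values were seen, was not called over all genes. It nevertheless lay at 0.97 to 1.60 on the tip arrays and at 0.01 to 0.20 on the stalk arrays. On the nonvascular arrays Vegfa was at −2.35, −2.06 and −0.34, and this variation enters the spread that the groups share. Its missing call is therefore no evidence that tip and stalk are alike in Vegfa. Chemokine genes had 2 of 22 higher and 0 lower (2 and 1 over the list alone, median 0.01, adjusted p = 0.677). TGF-beta and BMP genes (0 of 32, adjusted p = 0.923) and cell cycle genes (0 of 34, median 0.06, adjusted p = 0.585) had no called member. Ribosomal protein genes (0 of 36 called, adjusted p = 0.37) had a median of −0.02 but a mean of 0.07 and an upward test. They were called higher without tip replicate 1 (adjusted p = 0.00111) and with brightness in the model (0.00121), and lower with median centring (median −0.36, adjusted p = 1.57e-06, range 1.57e-06 to 0.988). The medians of the cell cycle, protease and chemokine lists became negative with median centring (−0.03, −0.01 and −0.05), and that of the VEGF family became 0.01 with brightness in the model.

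Lists of other retinal cells had small medians between tip and stalk. Ganglion cell genes were higher by a median of 0.15, with 1 of 19 passing, Nrn1 (2 over the list alone, adjusted p = 0.0235, and adjusted p = 0.339 with an estimated correlation). Nrn1 had an adjusted p of 0.0171, which was 0.0581 without stalk replicate 1 and 0.0596 without stalk replicate 3, 0.147 with median centring, 0.126 with the red channel alone and 0.177 with brightness in the model (range over alternatives 0.00535 to 0.177). This list's adjusted p was 0.138 without stalk replicate 3, 0.0615 without tip replicate 1, 0.0575 without tip replicate 6, 0.0697 from the Feature Extraction log ratios, 0.0682 from the deposited ratios, 0.0503 without background subtraction and 0.091 with fry. Lens crystallin genes were lower by a median of −0.06, with 1 of 18 passing, Cryab (1 over the list alone, adjusted p = 0.0245, and 0.28 with an estimated correlation). This call was lost without stalk replicate 2 (adjusted p = 0.062), tip replicate 3 (0.0743) or background subtraction (0.0503), with median centring (0.0864), with the red channel alone (0.427) and with brightness in the model (0.154). Cryab was not called with median centring (0.147) or with brightness in the model (0.112). Astrocyte genes (0 of 14 called, median −0.10, adjusted p = 0.142), photoreceptor genes (1 of 30 higher, median 0.02, adjusted p = 0.923) and amacrine, horizontal and bipolar cell genes (0 of 26, median −0.03, adjusted p = 0.474) were not called as lists. Nor were erythroid genes (0 of 11, median 0.05, adjusted p = 0.987), Mueller glia genes (1 of 18 lower, mean −0.03, adjusted p = 0.585) or microglia and macrophage genes (0 of 28, adjusted p = 0.923). The astrocyte genes S100b and Pdgfra, chosen here after their values were seen, nevertheless separated tip from stalk in opposite directions. S100b lay at 4.31 to 5.29 on tip and 5.66 to 5.98 on stalk arrays, Pdgfra at 2.77 to 3.39 and 2.31 to 2.62. Both varied among nonvascular arrays (1.89 to 4.45 and −1.18 to 1.93), which adds to the spread shared by the groups. The photoreceptor and erythroid medians became negative (−0.05 and −0.07) from the Feature Extraction log ratios, and the amacrine, horizontal and bipolar median became 0.05 from the red channel alone. The microglial list had a mean of 0.01 with a downward test, and the median of the Mueller glia list was 8.35e-05 with a downward test. Over the alternatives the medians were 0.12 to 0.40 for ganglion cell genes and −0.17 to −0.02 for lens crystallin genes, and those of the 15 lists not called lay between −0.36 and 0.17. Of 12 lists called with the preset correlation, 5 held with an estimated one, at much larger camera adjusted p. These were blood-retina barrier (0.0133), pan-endothelial (0.033), pericyte and smooth muscle (0.00549), venous (0.0342, lost with the red channel alone), and Norrin and Wnt signalling (0.00905).

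**Figure D2:**
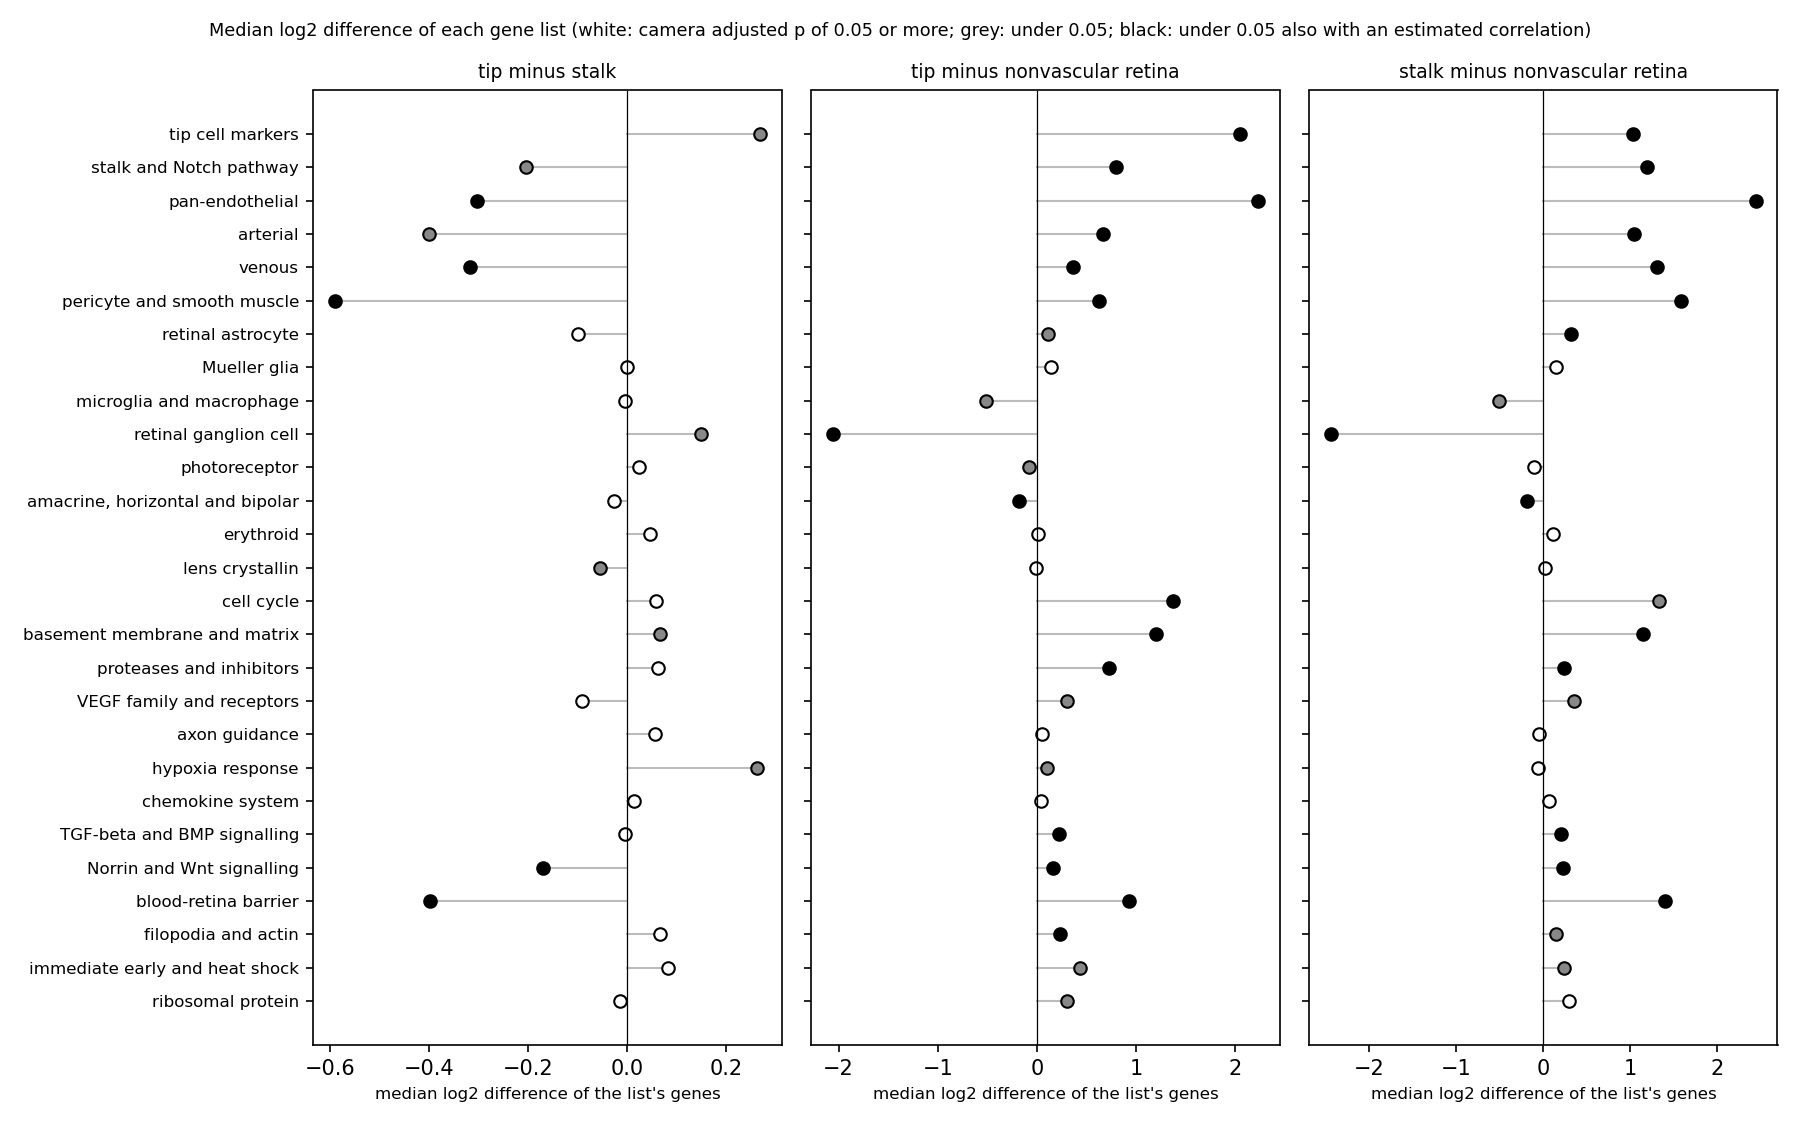
Median log2 difference (horizontal axis) of the 27 gene lists in the 3 comparisons, 1 point per list; white points have a camera adjusted p of 0.05 or more, grey points a smaller one, and black points a smaller one also with an estimated correlation. Between tip and stalk the lowest median, −0.59, is that of pericyte and smooth muscle genes.

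Both counts depended on single arrays. The 469 higher and 422 lower genes became 189 and 257 without stalk replicate 1, 201 and 268 without stalk replicate 3, and 254 and 273 without tip replicate 2. The higher count was 249 without tip replicate 3 and 1019 without tip replicate 6. Median centring gave 49 and 203, so 19.4% of calls were higher in place of 52.6%.

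Some genes were higher in tip than in both other groups, as a marker of tip cells within the retina would be. This held for 159 genes, 123 of them with a symbol, including Esm1, Cxcr4, Angpt2, Apln, Adm, Dll4, Kcne3, Chst1, Trp53i11, P4ha1 and Nid2. Independent lists of these sizes would share 52.2 genes. When the 6 tip arrays were divided so that each comparison had its own 3, over 20 divisions, a median of 33.5 genes (13 to 171) was higher in both, against 8.47 for independent lists. Without stalk replicate 1 the count of 159 was 82, without stalk replicate 3 it was 87, without tip replicate 2 it was 103 and without tip replicate 6 it was 286.

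The comparison of tip with nonvascular retina shows what separates samples labelled tip from the control samples. Endothelial transcripts were among the genes higher in tip: Esm1 was 83.3-fold higher, the prion-like gene Prnd 47.1-fold, the basement membrane gene Nid1 44.2-fold and the vascular surface gene Cd34 26.5-fold. Neuronal transcripts were lower, such as Elavl2, an RNA-binding protein of neurons (12.8-fold), Syt1, a synaptic vesicle protein (11.9-fold), and Mapt, the gene of the microtubule protein tau (11.7-fold). With the mean of a gene's probes the log2 differences of Elavl2 (−3.68) and Syt1 (−3.58) were −2.10 and −1.86. Of 32050 genes, 3566 were higher and 5389 lower (limma, adjusted p under 0.05), 1079 and 1530 by at least 2-fold. The naming rule gave 92 genes, all called.

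Cxcr4 was higher in tip than in nonvascular retina by 2.13 ± 0.23 (adjusted p = 1.35e-05) and Dll4 by 0.58 ± 0.07 (adjusted p = 5.17e-05), both in 6 of 6 tip arrays. Esm1 differed by 6.38 ± 0.17 (adjusted p = 2.03e-10), Flt1 by 4.11 ± 0.12 (adjusted p = 4.42e-10), Unc5b by 3.79 ± 0.22, Cdh5 by 3.63 ± 0.17, Angpt2 by 3.32 ± 0.32, Cxcl12 by 2.92 ± 0.44, Pdgfb by 2.72 ± 0.12, Jag1 by 2.04 ± 0.12 and Apln by 1.97 ± 0.13. With the mean of a gene's probes these were 1.14 for Cxcr4, 2.09 for Cdh5, 1.825 for Cxcl12, 1.38 for Pdgfb and 1.03 for Jag1, and from the Feature Extraction log ratios 1.101 for Dll4 and 3.08 for Jag1. In Cd34, tip replicate 1 lay at 2.18, below the other tip arrays (2.66 to 2.86). Kdr was 1.85-fold higher (adjusted p = 0.0103) with overlapping groups, and its adjusted p was 0.0733 without nonvascular replicate 1 and 0.0725 without nonvascular replicate 2, 0.164 from the Feature Extraction log ratios and 0.0767 with a normexp offset of 10 (range over alternatives 5.93e-06 to 0.164). In the red channel alone it differed by 1.93, against 0.89. Pecam1 was higher by 0.27 ± 0.08 (adjusted p = 0.018, and 0.1 without nonvascular replicate 2, range 0.00106 to 0.1), and by 0.85 from the Feature Extraction log ratios. Over the arrays of all groups its log2 ratios lay only at −0.26 to 0.23, and those of Flt4 at −0.07 to 0.21. Whether the probes of these genes respond to their transcripts was not tested. Flt4 was lower by 1.11-fold (adjusted p = 0.0321, range 0.0106 to 0.887), a call lost without nonvascular replicate 1 (0.145), nonvascular replicate 2 (0.136), tip replicate 3 (0.057) or tip replicate 4 (0.0629), from the Feature Extraction log ratios (0.269) or the red channel alone (0.887), with median centring (0.0818) and with only the 2 groups compared (0.06).

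Vessel lists were higher in tip than in nonvascular retina. Of 36 pan-endothelial genes 32 were higher (32 over the list alone, median 2.23, camera adjusted p = 3.86e-31), among them Egfl7, Sox7 and Icam2. Of 26 tip cell markers 17 were higher and 3 lower (18 and 3, median 2.05, adjusted p = 3e-13), of 23 stalk and Notch genes 17 were higher and 1 lower (19 and 1, median 0.79, adjusted p = 3.77e-11), and of 19 pericyte genes 13 were higher and 1 lower (15 and 1, median 0.63, adjusted p = 2.99e-09), among them Pdgfrb. Barrier genes had 15 of 22 higher and 1 lower (15 and 1, median 0.93, adjusted p = 7.32e-09), with Cldn5 at 3.20 ± 0.15. Arterial (6 of 11, 8 over the list alone, adjusted p = 8.39e-06) and venous genes (5 of 11, 8 over the list alone, adjusted p = 1.27e-04) were higher with 0 lower. Matrix genes had 23 of 32 higher and 1 lower (24 and 1, median 1.20, adjusted p = 1.37e-14), with the collagen gene Col4a1 at 3.92 ± 0.16, and cell cycle genes 30 of 34 higher (33 over the list alone, median 1.37, adjusted p = 4.02e-21), with Mcm6 at 1.78 ± 0.15. Proteases (15 of 24 higher, 2 lower, adjusted p = 3.26e-08), TGF-beta and BMP genes (14 of 32 higher, 4 lower, adjusted p = 7.28e-05), filopodia and actin genes (12 of 33 higher, 5 lower, adjusted p = 2.46e-04) and Norrin and Wnt genes (8 of 21 higher, 3 lower, adjusted p = 0.0246) were called upward. Over the alternatives the medians were 1.79 to 3.52 for pan-endothelial genes, 1.05 to 2.51 for tip cell markers, 0.74 to 1.30 for stalk and Notch genes, 0.605 to 1.05 for pericyte genes and 0.46 to 1.15 for barrier genes.

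Neuronal lists were lower in tip than in nonvascular retina. Of 19 ganglion cell genes 14 were lower and 0 higher (14 over the list alone, median −2.06, adjusted p = 5.7e-08), with Nefm at −2.31 ± 0.13. Of 26 amacrine, horizontal and bipolar cell genes 12 were lower and 1 higher (13 and 1, median −0.18, adjusted p = 1.11e-04), with the inhibitory transporter gene Slc32a1 at −3.54 ± 0.21. The median of this list was −0.35 to −0.10 over the alternatives. Some calls were lost with an estimated correlation: photoreceptor genes (11 of 30 lower, adjusted p = 0.0443, then 0.315), microglia and macrophage genes (12 of 28 lower, 1 higher, 0.00285, then 0.287), astrocyte genes (6 of 14 higher, 1 lower, 0.00285, then 0.0773), VEGF family genes (3 of 10 higher, 2 lower, 0.042, then 0.0773), hypoxia genes (8 of 24 higher, 3 lower, 0.042, then 0.315), immediate early and heat shock genes (16 of 26 higher, 4 lower, 0.00123, then 0.129) and ribosomal genes (3 of 36 higher, 2 lower, 0.0452, then 0.559). The remaining 15 of 22 called lists held, at camera adjusted p of 0.00243 (pan-endothelial) to 0.0454 (Norrin and Wnt), with cell cycle genes at 0.0355. The photoreceptor, VEGF family, hypoxia and ribosomal calls depended on single arrays as well, and all 4 were lost with only the 2 groups compared (adjusted p = 0.0635, 0.0528, 0.0576 and 0.0635). With median centring and with the red channel alone the photoreceptor (0.139 and 0.149), hypoxia (0.225 and 0.212) and ribosomal calls (0.079 and 0.138) were lost. The Feature Extraction log ratios ended the hypoxia (0.0714) and ribosomal calls (0.267), and the mean of a gene's probes the photoreceptor (0.0681) and ribosomal ones (0.111). Photoreceptor genes lost theirs without nonvascular replicate 3, stalk replicate 2 or 3, or tip replicate 1, 2 or 3 (adjusted p = 0.0508 to 0.137), and VEGF family genes without stalk replicate 2 (0.0508) or tip replicate 2 (0.057). Hypoxia genes lost theirs without nonvascular replicate 2 (0.171), stalk replicate 3 (0.0512), tip replicate 2 (0.057) or tip replicate 3 (0.0558), and their median of 0.10 became −0.10 with median centring. Of the arrays left out in turn, ribosomal genes kept theirs without nonvascular replicate 3, stalk replicate 4 or tip replicate 1, and without each other one had 0.0508 to 0.152. Mueller glia genes (6 of 18 higher, 3 lower) were called only without nonvascular replicate 3 (adjusted p = 0.0103, and 0.19 with all arrays). Erythroid (adjusted p = 0.185), lens crystallin (0.835), axon guidance (0.586) and chemokine genes (0.429) were not called, although erythroid genes were with median centring (0.0134) and with the red channel alone (0.0353), and axon guidance genes with fry (0.0218).

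The comparison of stalk with nonvascular retina asks the same of the samples labelled stalk. Basement membrane, mural and endothelial genes were among those higher in stalk: Nid1 was 40.2-fold higher, the endothelial receptor gene Cd93 35.8-fold, the mural transcription factor gene Foxf2 35.5-fold, Flt1 33.1-fold and the pericyte receptor gene Pdgfrb 32.4-fold. The neuronal genes Elavl2 (20-fold) and Mapt (16.9-fold) were lower. With the mean of a gene's probes the log2 differences of Cd93 (5.16) and Elavl2 (−4.32) were 3.14 and −2.45. Thy1, a surface protein of ganglion cells, was lower as well (adjusted p = 6.18e-05), and no fold is given because its spots were saturated in nonvascular retina. Of 32050 genes, 3604 were higher and 5952 lower (limma, adjusted p under 0.05), 1226 and 1907 by at least 2-fold. Of 95 genes given by the naming rule 91 were called.

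Cxcr4 differed between stalk and nonvascular retina by 0.67 ± 0.25 (adjusted p = 0.0628, in 4 of 4 stalk arrays) and Dll4 by 0.17 ± 0.08 (adjusted p = 0.136), neither of them called. Without nonvascular replicate 3 Cxcr4 was called (adjusted p = 0.0102), as it was without stalk replicate 3 (0.0077) and with array weights (0.0132, range over alternatives 0.0077 to 0.282). The Feature Extraction log ratios called both Cxcr4 (1.099, adjusted p = 0.0341) and Dll4 (0.47, adjusted p = 0.0454), as did the deposited ratios (0.0343 and 0.0455) and the red channel alone (1.04 and 0.47, adjusted p = 0.0126 and 0.0148). Whether these differences are smaller than those of tip was tested by tip minus stalk, in which both genes were called. Esm1 was higher by 3.51 ± 0.19, Jag1 by 3.11 ± 0.13, Kdr by 1.55 ± 0.25 (adjusted p = 0.000332), Angpt2 by 2.83-fold (adjusted p = 0.005) and Apln by 1.08 ± 0.14. Mfsd2a (4.00 ± 0.18) and Cldn5 (4.36 ± 0.16) were higher, as were Cdh5 (3.77 ± 0.19), Unc5b (3.31 ± 0.24), Cxcl12 (3.28 ± 0.48) and Pdgfb (2.45 ± 0.12). The mean of a gene's probes gave 1.60 for Jag1, 2.01 for Cdh5, 1.63 for Cxcl12 and 1.27 for Pdgfb, and the red channel alone 2.375 for Kdr. Flt4 (adjusted p = 0.893) and Pecam1 (adjusted p = 0.333) were not called, although Pecam1 was with median centring (0.0146).

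In stalk, pan-endothelial genes (31 of 36 higher, 32 over the list alone, median 2.45, camera adjusted p = 3.55e-32), pericyte genes (14 of 19 higher, 1 lower, median 1.59, adjusted p = 6.88e-12) and barrier genes (16 of 22 higher, 1 lower, 18 and 1 over the list alone, median 1.40, adjusted p = 6.88e-12) exceeded nonvascular retina. So did stalk and Notch genes (15 of 23 higher, 1 lower, adjusted p = 4.79e-11), tip cell markers (14 of 26 higher, 1 lower, adjusted p = 1.16e-09), arterial (6 of 11) and venous genes (7 of 11, both adjusted p = 1.58e-06), with Sox17, Gja4 and Emcn among them. Matrix genes (19 of 32 higher, 1 lower, adjusted p = 1.99e-11), proteases (13 of 24 higher, 1 lower, 9.32e-06), TGF-beta and BMP genes (12 of 32 higher, 4 lower, 2.6e-04), Norrin and Wnt genes (9 of 21 higher, 2 lower, 2.3e-04) and astrocyte genes (6 of 14 higher, 0 lower, 4.51e-04) were called upward. Ganglion cell genes (13 of 19 lower, median −2.44, adjusted p = 1.15e-07) and amacrine, horizontal and bipolar cell genes (12 of 26 lower, 1 higher, 0.00177) were called downward. Over the alternatives the medians of pericyte and barrier genes were 1.27 to 2.66 and 0.74 to 1.82. Of 19 called lists 14 held with an estimated correlation, at camera adjusted p of 0.00278 (pan-endothelial) to 0.0473 (astrocyte). Cell cycle genes (29 of 34 higher, median 1.33, adjusted p = 5.23e-17, then 0.055), VEGF family genes (5 of 10 higher, 1 lower, 0.0288, then 0.0583), microglia genes (11 of 28 lower, 1 higher, 0.0106, then 0.369), filopodia genes (10 of 33 higher, 6 lower, 0.0248, then 0.153) and immediate early genes (8 of 26 higher, 4 lower, 0.0416, then 0.369) did not. Immediate early genes also had an adjusted p of 0.0776 without nonvascular replicate 2, 0.0697 without stalk replicate 2 and 0.0605 without stalk replicate 4, and one of 0.0551 with a normexp offset of 10. Median centring ended the VEGF family (0.0683), filopodia (0.107) and immediate early calls (0.261), and the Feature Extraction log ratios the filopodia (0.0661) and immediate early ones (0.0823). Filopodia genes had 0.084 with the mean of a gene's probes and 0.0551 with only the 2 groups compared, where VEGF family genes had 0.05.

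Hypoxia genes were not called as a list between stalk and nonvascular retina (4 of 24 higher, 8 lower, median −0.05, mean 0.03, downward test, adjusted p = 0.798), although the stress gene Ndrg1 fell by 1.91 ± 0.22 and Pgk1 fell by 1.06 ± 0.14 (−0.68 in the red channel alone). Axon guidance (adjusted p = 0.798), chemokine (0.682), erythroid (0.214), lens crystallin (0.432, median 0.02, mean −0.00287 and an upward test) and ribosomal genes (0.214) were not called, although erythroid genes were with median centring (0.0281). Photoreceptor genes (0.0768) were called without nonvascular replicate 2 (0.00371), from the Feature Extraction log ratios (0.0442) or the deposited ratios (0.0464) and with fry (0.000792), and Mueller glia genes (0.111) without nonvascular replicate 3 (0.0046). Ribosomal genes were called without tip replicate 1 (0.015), with median centring (median 0.56, adjusted p = 0.00103) and with only the 2 groups compared (0.0356). Over all alternatives the medians of the 8 lists not called lay between −0.25 and 0.56.

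**Figure D3:**
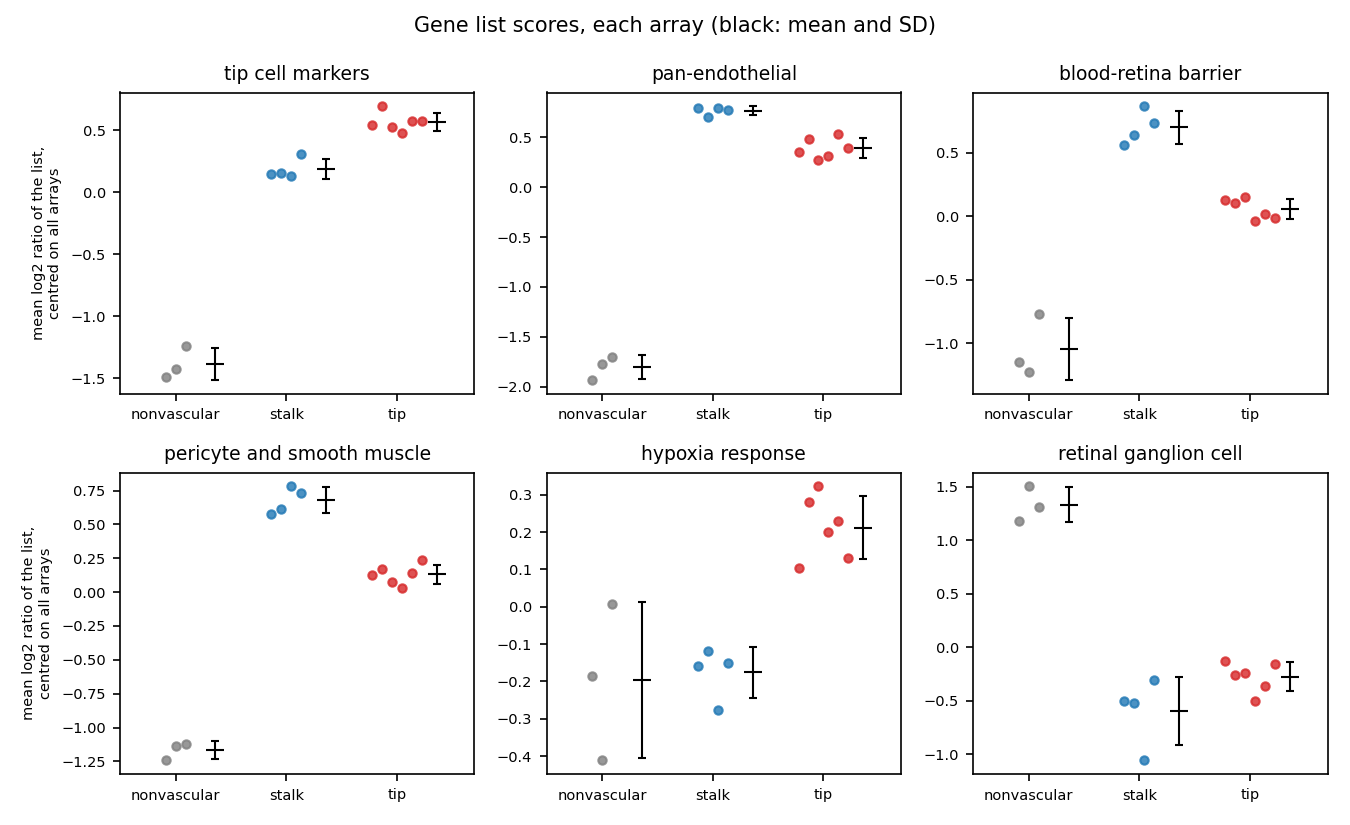
Mean log2 ratio of the genes of 6 lists on each array, centred on the mean of all arrays (vertical axis, each panel with its own scale), for nonvascular retina (3 arrays), stalk (4) and tip (6), 1 point per array. Pericyte scores average 0.13 in tip and 0.68 in stalk, and hypoxia scores 0.21 in tip and −0.18 in stalk.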

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

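The tests of nonvascular RNA and of array brightness were chosen after the data were seen, and those of other splits of the samples before. The lists weighed below had already been called on the same arrays. The permutation p-values of their scores are not adjusted over the lists and add no independent support.

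Pan-endothelial genes were lower in tip than in stalk: their mean score was 0.392 ± 0.098 in tip (SD, 6 arrays) and 0.769 ± 0.044 in stalk (SD, 4 arrays). The exact permutation test gave p = 0.00476, two-sided and not adjusted, the smallest that 210 rearrangements can give. More RNA from nonvascular retina in the tip samples would have to make up 19.0% of them and would raise the 439 genes that are at least 4-fold lower in stalk than in nonvascular retina by 0.906. They rose by a median of 0.296 (0.109 to 0.509 over the tip arrays). If the nonvascular samples resemble the retina beside the tips, this excludes nonvascular RNA as the whole cause, narrowly in the red channel alone (list median −0.138, needed rise 0.572, tip arrays up to 0.562). The rise corresponds to a share of 4.95% and an endothelial shift of −0.073. The 439 genes were chosen for low values on the same stalk arrays, which by itself can raise this share. Without stalk replicate 3 the rise was 0.198. With brightness in the model the difference went from −0.377 ± 0.059 to −0.291 ± 0.056 (SE), so brighter tip arrays cannot be told apart from the groups as a part of it, although the 2 tip arrays as dim as the stalk arrays scored 0.395 and 0.530, below all stalk arrays (0.704 to 0.799). The position of the cells in the sprout, a different mix of cell types in the samples and the scan order stay open and untested.

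Pericyte and smooth muscle genes were lower in tip as well (0.132 ± 0.072 against 0.677 ± 0.097, SD, 6 and 4 arrays, exact permutation p = 0.00476, two-sided, not adjusted, the smallest possible). Nonvascular RNA would need a share of 33.6% and a rise of 1.348 in the same 439 genes, far above the 0.296 measured. With the mean of a gene's probes the needed share was 18.7% and the needed rise 0.882, in 357 genes that rose by 0.297. With brightness in the model the difference was −0.475 ± 0.051, against −0.545 ± 0.051 without, so brightness is excluded as the whole cause. With the most intense probe of each gene, pericyte genes fell further than pan-endothelial genes (difference of the scores −0.168, exact permutation p = 0.0286, two-sided, not adjusted). With the mean of a gene's probes the list medians were −0.299 for pericyte and −0.304 for pan-endothelial genes, so the further fall was not seen. This difference therefore cannot exclude a single dilution of both by the same share. Fewer mural cells at the tips may be the reason for the lower pericyte genes, as a hypothesis from the group labels that no test here addressed, and scan order is confounded with it.

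Hypoxia response genes were higher in tip (0.212 ± 0.085 against −0.176 ± 0.069, SD, 6 and 4 arrays, exact permutation p = 0.00476, two-sided, not adjusted, the smallest possible). The call of this list was lost with an estimated correlation between genes (camera adjusted p = 0.0573). Of the 6 members that rose, 2 (Adm and P4ha1) were higher than in both other groups, which RNA like that of the nonvascular samples cannot give. Whether the retina beside the tips resembles those samples was not tested, and Adm varied among them (−1.98, −2.19 and −0.54). Of the other members, the least demanding, Pgk1, would need a share of 59.7% and a rise of 1.905 in the nonvascular genes, against 0.296 measured. With brightness in the model the difference was 0.343 ± 0.094, against 0.388 ± 0.076 without, so that brightness as a part of it stays open; the 2 dim tip arrays scored 0.131 and 0.231, above all stalk arrays (−0.277 to −0.118). Lower oxygen at the front of the growing vessels is a candidate explanation that no test here addressed.

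Other splits of the same samples were counted for each comparison. Of 100 splits drawn from the 210 possible for tip and stalk, 1, the real one, gave as many genes (891, the highest other 397). For tip and nonvascular retina this was 1 of 84 (8955, the highest other 15), and for stalk and nonvascular retina 1 of 35 (9556, the highest other 4181). The real split thus gave the most genes in each comparison. Ranking first among 100, 84 or 35 splits is the most that this count can show, so chance is unlikely but not excluded. The count also takes the arrays as exchangeable, which the labels and the scan order do not settle.

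Single arrays far from the rest of their group were found in 20 of 354 groups of values tested (150 genes and 27 lists, in the tip and stalk groups), which is 5.65%. The rule asks that the gap to the nearest other array, as a share of the group's range, exceed Dixon's critical value. Of 20000 simulated groups of independent normal values, 4.92% met it with 4 arrays and 5.03% with 6, about 1 in 20. Tip replicate 1 had 6 of these. On it the ribosomal protein score was −0.433 (other tip arrays 0.08 to 0.26) and Rps2 was at −1.88 (−1.09 to −0.76). On the same array Vim was at −1.62 (others −0.77 to −0.48), Klf4 at −3.44 (−2.82 to −2.52), Cd34 at 2.18 (2.66 to 2.86) and Ctsh at 2.24 (1.58 to 1.77). Tip replicate 6 was low for Flt1 (1.91, others 2.19 to 2.34) and high for Birc5 (0.56, others 0.34 to 0.40). Tip replicate 5 was high for Tyms (0.31, others −0.03 to 0.08) and tip replicate 3 low for Cx3cl1 (−2.16, others −1.57 to −1.46). Stalk replicate 4 was high for Esm1 (2.25, others 1.59 to 1.65), for Sox9 (2.28, others 1.69 to 1.71) and for the tip cell marker score (0.307, others 0.13 to 0.16), and low for Sox7 (3.79, others 3.98 to 4.02). Stalk replicate 3 was low for Mllt11 (−1.50, others 0.51 to 0.71) and C1qb (0, others 0.11 to 0.13) and high for Myo10 (1.18, others 0.70 to 0.72). Stalk replicate 2 was low for Vegfa (0.01, others 0.18 to 0.20). Stalk replicate 1 was high for S100b (5.98, others 5.66 to 5.71) and low for the score of amacrine, horizontal and bipolar cell genes (−0.175, others −0.13). No explanation of these single values was tested.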

How the results depend on the processing

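Brightness as a covariate was chosen after the data were seen. The 469 higher and 422 lower genes of tip against stalk, and the 159 higher than in both other groups, came to 311, 387 and 100 from the Feature Extraction log ratios, 297, 385 and 98 from the deposited ratios, 215, 476 and 100 from the red channel alone, 49, 203 and 27 with median centring, and 77, 149 and 45 with brightness in the model. Median centring also gave 2181 in place of 3566 genes higher in tip than in nonvascular retina. The cause was not tested. Of the calls between tip and stalk, 52.6% were higher, against 19.4% with median centring, 31.1% with the red channel and 34.1% with brightness, and for tip against nonvascular retina 39.8% against 28.0% with median centring. No scaling moved the median of all genes by over 0.1. Leaving out 1 array gave 189 to 1019 genes higher and 257 to 582 lower in tip than in stalk, and 82 to 286 higher than in both. It gave 2692 to 3838 higher and 4436 to 5406 lower for tip against nonvascular retina, and 2773 to 3696 and 5032 to 5991 for stalk. Aquantile normalization leaves log ratios unchanged, so it tests nothing here. Replicate numbers did not pair the samples (deviations of 10 same-numbered pairs correlated at −0.144 to 0.082), and the replicate block gave 379 higher and 291 lower genes. The scan date block equals leaving out tip replicate 5, and a slide block was not run because each slide held 1 array. Of 1800 values of named genes between tip and stalk, 1663 stayed on their side of the threshold, 133 fell below it with the same sign, 4 rose above it and 0 changed sign with a call on either side; 4 of the 1663 changed sign uncalled. For tip against nonvascular retina it was 2694, 65, 0 and 1 of 2760 (0 uncalled changes of sign), where Rps2 reversed to −0.02 as a mean of probes that point both ways, and for stalk 2819, 21, 10 and 0 of 2850 (6 uncalled changes). Of the 864 list values per comparison, 808, 810 and 833 stayed on their side of the threshold, 34, 5 and 7 of these with an uncalled change of test direction, and the ribosomal list reversed to −0.363 between tip and stalk with median centring; the cause was not tested. The alternatives did not end the calls of Cxcr4 (adjusted p up to 0.0449), Esm1 (0.000761), Angpt2 (0.0485), Mfsd2a (0.000395) or Lsr (0.000761) between tip and stalk. Signal over background limits genes such as Dkk2, well above background on 2 of 6 tip arrays.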

Other observations

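The 6 gene families reported here, their tests and the genes named for them were chosen after the data were seen.

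Of 21 glycolysis enzymes, 7 were higher in tip than in stalk and 0 lower, among them Pkm (1.27 ± 0.23), Tpi1 (0.89 ± 0.10) and Pfkl (0.87 ± 0.15, SE). This family overlaps the hypoxia list described before, in 7 of the 21 members and in 4 of the 7 that were called. Without the 8 members that are in any of the 27 lists, 3 of 13 were higher and 0 lower (median 0.11, camera adjusted p = 0.00345 over the 6 families, and adjusted p = 0.142 with an estimated correlation). The median of all 21 was 0.31, and 0.09 with median centring. Against nonvascular retina the 21 enzymes were lower in stalk (13 lower and 1 higher, median −0.54, −0.77 to −0.35 over the alternatives, adjusted p = 1.13e-04, and 0.0711 with an estimated correlation) and in tip (8 lower and 2 higher, median −0.16, −0.26 to −0.11 over the alternatives, adjusted p = 0.034, then 0.145). Genes for protein folding and transport in the endoplasmic reticulum had 3 of 70 higher in tip than in stalk and 0 lower (median 0.17, and 0.08 in the red channel alone, adjusted p = 2.56e-06, and 0.188 with an estimated correlation), namely Kdelr3 (0.59 ± 0.13), Pdia6 (0.43 ± 0.10) and Copa (0.39 ± 0.07).

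Of 314 solute carrier genes, 9 were higher and 13 lower in tip than in stalk (median 0.01 with a downward test, adjusted p = 0.653). The zinc and metal transporter Slc39a8 (−1.67 ± 0.16), the iron exporter Slc40a1 (−1.36 ± 0.18) and the taurine transporter Slc6a6 (−1.14 ± 0.16) were lower, and Slc16a6 (0.84 ± 0.11) and the phosphate transporter Slc20a1 (0.79 ± 0.12) were higher. Interferon-induced genes had 4 of 61 lower and 1 higher (median −0.04, −0.10 to −0.02 over the alternatives, adjusted p = 0.0112, and 0.386 with an estimated correlation), with Irgm2 (−1.19 ± 0.24), Ifi27 (−1.13 ± 0.10), Gbp3 (−1.02 ± 0.19) and Ifitm3 (−0.64 ± 0.08) lower and Irf8 (1.02 ± 0.15) higher. Of 76 potassium channel genes, Kcne3 was higher and Kcnj8 (−0.71 ± 0.12), a pericyte channel, and Kcnab1 (−0.55 ± 0.11) were lower (median −0.01, adjusted p = 0.622). Proteasome subunits had 0 of 38 called (median 0.05, adjusted p = 0.45) and a negative median, −0.08, from the red channel alone. Medians of the solute carrier and potassium channel families changed sign as well between alternatives (−0.08 to 0.04 and −0.11 to 0.02).

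Nonvascular replicate 3 stood apart from the other nonvascular arrays. It lay at −66.2 on the first principal component, the others at −89.0 and −90.2. Its mean score was −0.128 for astrocyte genes (others −1.022 and −0.915) and 0.277 for Mueller glia genes (others −0.399 and −0.741). Groups of 3 arrays were not tested for such values.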
